A study of Mus musculus with 4 samples.

How the data were processed

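The data were 4 one-colour Agilent mouse expression arrays (Cy3, 44397 spots each, of which 43020 were not controls, with 39429 different probes), 1 for each combination of tissue (liver, WAT) and genotype (wild type, Pnpla7-/-). Per the labels, each array held RNA pooled in equal amounts from 5 animals at 4 weeks of age, and the labelling reaction started from 200 ng of it. The protocol in the labels names livers as the source of the RNA for all 4 samples, and neither the fat depot nor the sex of the animals is given in the sources used here. All 4 arrays lay on 1 slide with 1 scan time, so slide and scan were the same for every group.

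Per the file headers and the submitters' processing notes, the deposited scanner files hold spot intensities from Agilent Feature Extraction 11.0.1.1. Its processed signal is an intensity corrected for background with a fitted surface and for multiplicative trends, and it was not normalized between arrays. A further table of the whole series held the authors' values on a linear scale. Set against the scanner files, each of its columns was the processed signal divided by 1 constant per array, equal to the 75th percentile in that file's header (1470, 1764, 1690 and 1613 for wild-type liver, labelled-knockout liver, wild-type WAT and labelled-knockout WAT), with no centring of genes. Its column medians were 0.0737, 0.0751, 0.0876 and 0.0875. Scale, centring and direction were thus settled, and the table was used as an alternative. The probe annotation in the files is on the mm9 build.

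From these intensities, the log2 of the processed signal minus the array's 75th percentile over spots other than controls was computed. Spots marked as non-uniform or as population outliers were left out (between 78 and 109 outlier spots per array), and the spots of a probe were averaged. A probe was measured in a pair when more than a 0.5 share of its spots was well above background on both arrays and 0 were saturated. A gene's log2 ratio was the mean over its measured probes. Among genes that reached 2-fold with several probes, 55 of 56 in liver and 112 of 113 in WAT had probes of 1 sign, and 36 and 77 had every probe past 2-fold. In 52 genes of liver and 68 of WAT the probes had opposite signs and differed by more than 1 on the log2 scale, as for some genes of multigene families. Probe names were updated through a RefSeq gene table of the GRCm38.p6 assembly, used for names only. The accession named 27228 probes, the symbol 3581 and a synonym 565, and 8055 kept the name in the file. In all 28400 probes had a gene symbol, for 19819 genes. Probes without one were counted but not named.

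Directions were taken as labelled knockout over wild type. With 1 array per group no test was made. Genes were counted where the ratio reached 2-fold in either direction. Errors came from the scanner software's error model (a preset multiplicative error of 0.1), from 399 probes printed as 10 spots (median SD of the log2 ratio 0.09 in liver and 0.08 in WAT) and from different probes of a gene (pooled SD 0.20 and 0.23). Signal over background, as the 75th percentile over the mean of negative controls, was between 193 and 271. A gene well above background on 1 array alone was given as a lower bound, the bright probe's level against the higher of the dim array's lowest signal among probes well above background and the probe's own signal there.

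For 39 gene lists, the median log2 ratio was set against 10000 random lists of the same size drawn from 20 bins of mean expression, and given as a percentile. Lists with under 5 measured genes had no percentile, which left 38, and Pnpla7 was kept out of all lists. A percentile describes these arrays and is not a test across animals. Lists, groups, the 2-fold limit and the rule for named genes were fixed before the data were examined. Named genes were Pnpla7, Pnpla6 and Pnpla8, up to 10 of the highest and 10 of the lowest ratios per tissue among genes at least 2-fold different with probes of 1 sign and a level above the 25th percentile, up to 4 members of each list with the largest ratios, up to 5 genes per direction with the largest bounds, up to 5 genes per pattern shared by the tissues, and the genes that report sex. Some genes that met this rule are not reported here. Alb, Apoa1, Cyp2e1, Trf, Tat, Zic1, Letmd1 and Adrb3 in WAT, Afp and H19 in liver, and the further genes named beside a count of 17 opposite genes, were chosen after their values were seen.

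The steps were tested on simulated data made from the real wild-type levels with the spread between probes as noise. In the simulated liver pair (14408 genes), 50 of 50 genes planted at 3-fold, 50 of 50 at 4-fold, 30 of 50 at 2-fold and 1 of 50 at 1.5-fold were called, with 0 of 14208 unchanged genes. In the simulated WAT pair (14905 genes), the numbers were 50, 50, 16 and 1 of 50, with 0 of 14705 unchanged genes. Of 100 random lists, 1 stood apart in the liver simulation and 4 in that of WAT, and 20 of 20 lists shifted by a log2 of 0.25 did so in each. The noise had the same SD at all expression levels and held no variation between arrays, pools or animals. The 2-fold limit lies far outside such noise, so the absence of false calls was fixed by the setting. It gives no rate of false calls for the real pairs.

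The alternatives were normexp background correction (offset 50), quantile normalization of the pair, the median of each array, the 75th percentile over probes measured on both arrays, loess within the pair, no filter on background, a stricter filter on dim probes, the brightest probe per gene, flagged spots kept, the authors' table, fold limits of 1.5 and 3, unmatched random lists and the mean of a list. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.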

Results

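Gene expression was measured in liver and in white adipose tissue (WAT) of mice with a disrupted Pnpla7 gene (Pnpla7-/-) and of wild-type mice, all on the C57BL/6N background and 4 weeks old. PNPLA7 is a lysophospholipase that acts on lysophosphatidylcholine, and the series as titled concerns the supply of choline from phosphatidylcholine in liver and its use by the methionine cycle. Each of the 4 groups had 1 array, hybridised with Cy3-labelled RNA pooled in equal amounts from 5 animals. There was therefore no replicate check of any difference, no test across samples was made and no p-value is given. The number of arrays limits the precision. The share of spots well above background was 65.5% for wild-type liver, 68.2% for labelled-knockout liver, 72.6% for wild-type WAT and 68.1% for labelled-knockout WAT, and 0 spots were saturated. Differences are given as log2 ratios of the array labelled knockout to the wild-type array of the same tissue, counted where they reached 2-fold. The scanner software's error model put the median error of a log2 ratio at 0.20 in both tissues, a value largely set by its preset multiplicative error of 0.1. Repeat spots of a probe had a median SD of 0.09 in liver and 0.08 in WAT. Probes of the same gene differed by a pooled SD of 0.20 in liver and 0.23 in WAT. These errors cover spots and probes only, not the variation between animals.

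Pnpla7 transcript was lower in the labelled-knockout WAT and nearly level in liver. Its only probe, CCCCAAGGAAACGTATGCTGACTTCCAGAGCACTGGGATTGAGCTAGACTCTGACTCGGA, starts at base 4129 of the transcript and lies on chromosome 2 between 24908961 and 24909192 on the mm9 build, per the scanner files. In liver the signal was 9.04 times the array's 75th percentile in wild type and 7.98 times in the labelled knockout, a log2 ratio of -0.18 with a model error of 0.20. In WAT it was 0.739 and 0.372 times the 75th percentile, a log2 ratio of -0.99 with a model error of 0.20, or 50.4% of wild type. The part of the gene that was removed is not given in the sources used here, and a probe outside that part checks nothing. The directions below therefore rest on the labels, and the arrays are called labelled knockout. The related phospholipase genes Pnpla6 and Pnpla8 had log2 ratios of 0.23 and -0.23 in liver and 0.05 and 0.37 in WAT.

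The tissue labels were checked with marker lists. On the wild-type arrays all 25 hepatocyte markers were lower in WAT than in liver, with a median log2 difference of -7.70, and 26 of 29 measured adipocyte genes were higher, with a median of 4.12. On the labelled-knockout arrays the medians were -8.64 and 3.30. Xist, transcribed from the inactive X chromosome, was well above background on all 4 arrays with both of its probes. The Y-linked genes Ddx3y, Eif2s3y, Uty, Kdm5d, Usp9y and Zfy1 had 7 probes, of which 0 were well above background on any array. The probe of Sry, a further Y-linked gene, was well above background on all 4 arrays, at between -5.38 and -4.95 on the log2 scale. Xist had log2 ratios of -0.30 in liver and -0.35 in WAT.

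In labelled-knockout liver the lowest ratios were those of Cyp2b13 and A1bg, both known to be female-biased, and the highest those of Ubd and Tff3. Cyp2b13, a cytochrome P450, was 17.4-fold lower and A1bg 13.8-fold lower. Hao2, a peroxisomal oxidase, was 7.25-fold lower, Orm3, an acute phase protein, 7.23-fold lower and Slc22a26 6.72-fold lower. Sult2a7, Lrtm1, Cyp3a44, Sult2a3 and Cyp3a41b were between 5.43 and 6.46-fold lower. Ubd, a ubiquitin-like protein induced by inflammation, was 21.8-fold higher, Tff3 18.2-fold and Sprr1a 14.7-fold higher. Cbr3, Asns (asparagine synthetase), Elovl7, Fgf21 (a hepatic hormone of fasting and amino acid stress), Tceal5 and Cgref1 were between 7.33 and 10.8-fold higher. Near-identical family members such as the Sult2a, Cyp2b, Cyp3a and Mup genes can share probe signal, so a ratio given for one member is uncertain as to the member.

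**Figure D1:**
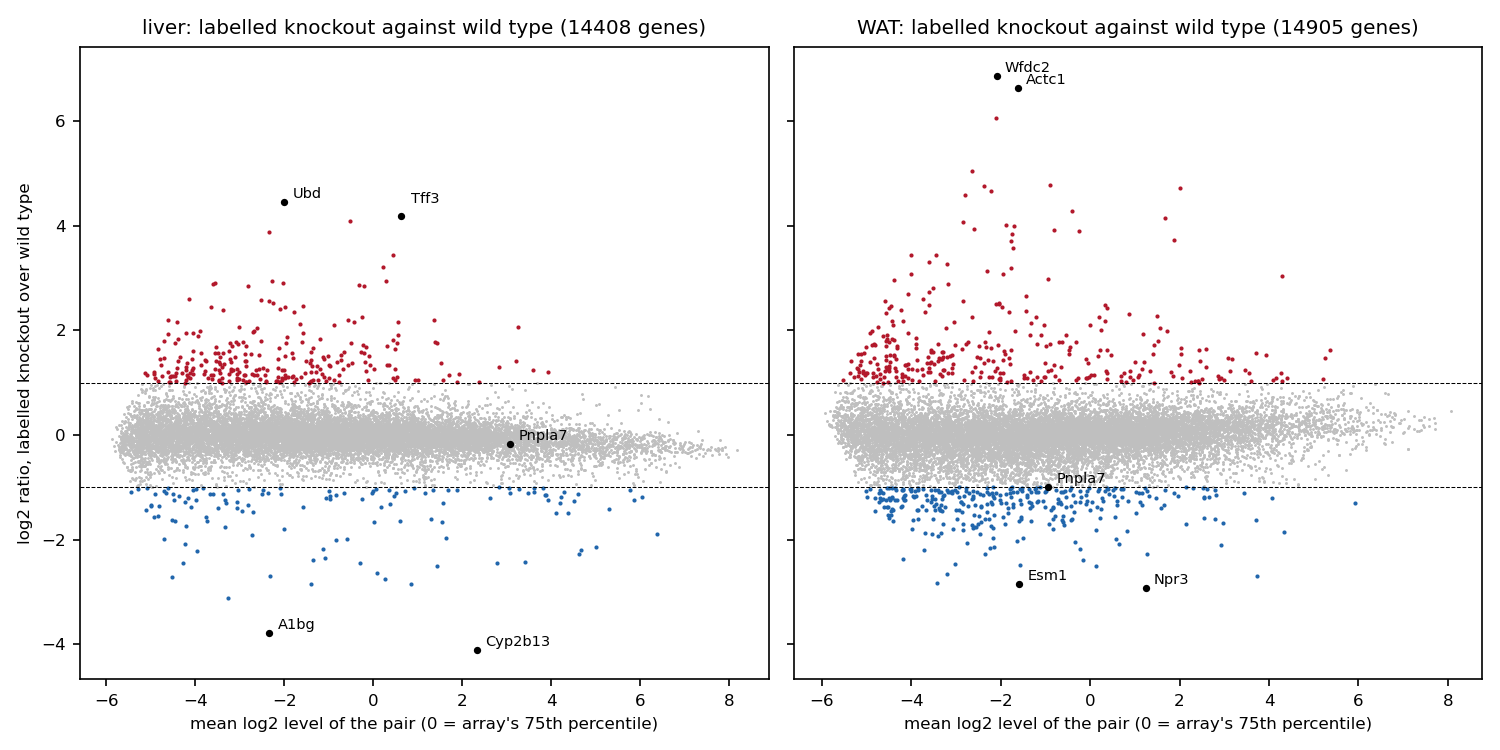
Each point is a gene, with the mean log2 level of the wild-type and labelled-knockout arrays on the x axis and the log2 ratio of labelled knockout to wild type on the y axis, for liver on the left and WAT on the right. Genes at least 2-fold higher are red and at least 2-fold lower blue, outside the dashed lines at -1 and 1. Pnpla7 lies at -0.18 in liver and at -0.99 in WAT.

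Of 14408 genes measured in liver, 255 were at least 2-fold higher and 126 at least 2-fold lower in the labelled knockout, and the median log2 ratio of all genes was -0.03. With normexp background correction in place of the scanner software's processed signal the counts were 98 higher and 210 lower, so the share of higher among the differing genes went from 66.9% to 31.8%, and the median of all genes from -0.03 to -0.18. The balance of higher against lower genes in liver thus depended on this setting. It also adds an offset of 50 to the signal before the arrays are scaled. Offset and background correction were not varied apart, so the change cannot be assigned to either.

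Genes of cell division stood out as a group in labelled-knockout liver. Of 28 measured genes of the proliferation list, 20 were at least 2-fold higher, 0 were 2-fold lower, and the median log2 ratio was 1.34 (0.85 with normexp), above all of 10000 random lists of the same size matched on expression level. Examples were Cdc20 (log2 ratio 1.83) and Ube2c (1.66), which drive the exit from mitosis, the cyclin Ccnb1 (1.61) and the mitotic kinase Plk1 (1.53). Ccnb1 was at 0.46 with normexp. Lists are said to stand apart where their median lay among the lowest or highest 2.5% of such random lists. About 1.9 of the 38 lists with enough measured genes would do so by chance in each tissue, and genes of a pathway vary together, which makes their percentiles more extreme than those of unrelated genes.

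Amino acid stress genes, targets of the transcription factor ATF4, were also higher in liver. Among 28 measured members 7 were at least 2-fold higher and 0 lower, with a median of 0.28 that was above all random lists. Asns was 9.32-fold, Fgf21 7.67-fold, Phgdh, the first enzyme of serine synthesis, 5.96-fold and Mthfd2, a mitochondrial folate enzyme, 4.60-fold higher. Mthfd2 was at a log2 ratio of 0.24 with normexp against 2.20. The unfolded protein response list did not stand apart (median -0.11, percentile 29.0).

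Sex-biased liver genes differed in opposite directions. The female-biased list had a median log2 ratio of -0.90, below all random lists, with 12 of 27 measured genes at least 2-fold lower and 0 higher. Cyp2b13 (-4.12), A1bg (-3.78), Sult3a1 (-3.12) and Hao2 (-2.86) were the lowest. The male-biased list had a median of 0.26 (0.13 with normexp), above all random lists, with 4 of 23 genes at least 2-fold higher and 1 lower. Its leading members were Slco1a1 (2.26), an organic anion transporter, Hsd3b5 (1.76) and Cyp4a12b (1.74), while Sult5a1 was lower (-1.38). Cyp4a12b was at 0.80 with normexp.

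Genes of phosphatidylcholine and choline metabolism showed no common difference in liver. Of 32 measured genes, 0 reached 2-fold, and the median of -0.08 lay at percentile 30.7. The largest log2 ratios were 0.97 for Gdpd1, 0.69 for the choline kinase Chka, -0.64 for the glycerophosphocholine phosphodiesterase Gpcpd1 and 0.62 for Enpp2. The methionine cycle and one-carbon list lay below all random lists with a median of -0.35, and 30 of its 32 measured genes were within 2-fold. Shmt1 (-0.72) and Gnmt (-0.71), the latter a methyltransferase that uses S-adenosylmethionine, were among the lower members. The 2 members at least 2-fold higher, Mthfd2 (2.20) and Mthfd1l (1.59), are mitochondrial folate enzymes. With the mean of the list in place of its median the percentile was 14.7, and the list no longer stood apart.

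The fatty acid synthesis, bile acid and xenobiotic enzyme lists were lower in labelled-knockout liver by their medians, while cholesterol synthesis was slightly higher. The fatty acid synthesis list had a median of -0.48, below all random lists, although only Me1 (-1.10) was 2-fold lower and Scd2 (1.65), a stearoyl-CoA desaturase, was 2-fold higher among 23 genes. Me1 was at -0.98 with quantile normalization. The cholesterol synthesis list had a median of 0.08 at percentile 99.9 with 25 of 25 genes within 2-fold, and lay at percentile 97.0 among unmatched random lists. Bile acid genes had a median of -0.43 (-0.22 with quantile normalization), below all random lists, with Cyp8b1, the sterol 12-alpha-hydroxylase, at -1.38, Slco1a1 at 2.26 and Abcc4 at 1.01 (0.72 with normexp). The bile acid list was at percentile 2.53 with the mean of the list. Xenobiotic enzymes had a median of -0.59, also below all random lists, with 7 of 30 genes at least 2-fold lower, among them Cyp2b10 (-1.42), Gstt3 (-1.18) and Cyp2c37 (-1.15), and 1 higher, Gsta2 (1.21). The gluconeogenesis and glucose regulation list stood apart with a median of -0.24 (percentile 0.44), or -0.12 with quantile normalization. It had 1 gene 2-fold lower, Pklr (-1.08), the liver pyruvate kinase. Pklr was at -0.97 with normexp. PPAR alpha targets had no settled direction, with a median of -0.19 (percentile 6.17, and 0.020 among unmatched random lists) and a mean of 0.03 (percentile 99.9 with the mean of the list), and with 4 of 39 genes at least 2-fold higher, among them Fgf21 (2.94) and the lipid droplet gene Cidec (2.46).

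Markers of other cell types in the liver pools moved in several directions. Macrophage and myeloid markers had a median of 0.17 (0.09 with normexp), above all random lists, with Trem2 (2.45), a receptor of lipid-laden macrophages, and Itgax (1.26) the highest. Itgax was at 0.62 with normexp. Extracellular matrix genes had a median of 0.28 (0.07 with normexp), above all random lists, with 1 of 26 genes at least 2-fold higher, Timp1 (1.78), which was at 0.85 with normexp. Erythroid markers had a median of -0.63, below all random lists, with Klf1 at -1.04 (-0.98 with the 75th percentile over probes measured on both arrays) and Slc4a1 at -0.96, while Tfrc was at 0.90. The T and B cell list had a median of -0.16 (percentile 0.34), with Cxcl13 at -1.75, and was at percentile 7.37 with normexp. Hepatocyte markers (median -0.28, percentile 3.18, below all unmatched random lists but at -0.01 and percentile 49.9 with quantile normalization), endothelial and stellate markers (-0.02, percentile 60.2) and biliary markers (-0.20, percentile 2.77) did not stand apart. Acute phase proteins had a median of -0.30 (percentile 0.030), or -0.12 with quantile normalization, with 5 of 28 genes at least 2-fold lower, among them Orm3 (-2.85), Hamp2 (-1.89) and the metallothionein Mt1 (-1.49), and 1 higher, Saa3 (1.76). The brightest probe of Mt1 read -0.23.

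**Figure D2:**
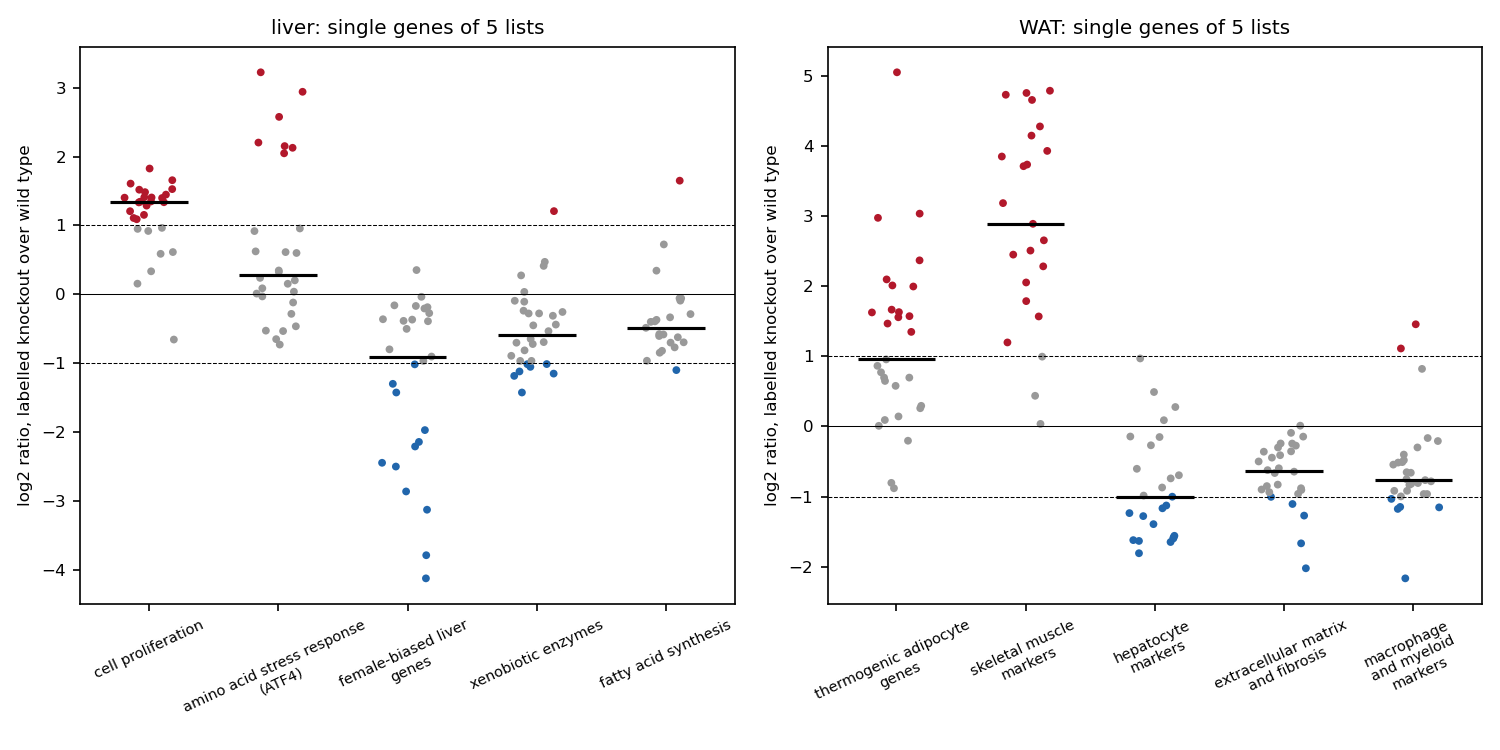
Log2 ratios of labelled knockout to wild type (y axis) of the measured genes of 5 lists in liver (left) and 5 lists in WAT (right), 1 point per gene, with the list's median as a bar. Red and blue points lie at least 2-fold higher or lower, outside the dashed lines. Medians range from -0.90 for female-biased genes to 1.34 for cell proliferation in liver, and from -1.002 for hepatocyte markers to 2.89 for skeletal muscle markers in WAT.

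Genes seen on 1 liver array alone have only a bound. The bound was at least 2-fold for 85 genes seen on the labelled-knockout array and for 42 seen on the wild-type array. In labelled-knockout liver Krt20 was at least 9.58-fold, Gpnmb, a gene of lipid-loaded macrophages, at least 8.61-fold, Mab21l3 at least 7.75-fold and the growth factor Areg at least 7.14-fold above wild type. In the other direction, Rnase11 was at least 8.21-fold and Ifi44l at least 7.24-fold above the labelled knockout. With normexp and its offset of 50 the 2 counts were 1 and 145, so these bounds depend on that setting.

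In labelled-knockout WAT the highest ratios included those of muscle genes, of Elovl3 and of Wfdc2. Wfdc2, an epithelial secreted protein, was 117-fold higher (its probes differed, at log2 ratios of 5.73 and 8.01, and its wild-type level of -5.52 was dim), Actc1, the cardiac alpha-actin, 99.7-fold, Plekhs1 66.4-fold and Elovl3, a fatty acid elongase of brown fat, 33.2-fold higher. The muscle genes Pvalb, Ttn, Myh4, Ckm and Tnnt3 were between 19.4 and 27.7-fold higher, and the tight junction gene Cldn3 was 23.9-fold higher. Wild-type levels were also dim for Actc1 (-4.93), Plekhs1 (-5.13), Elovl3 (-5.18), Cldn3 (-5.08), Ttn (-4.75) and Ckm (-4.55). The size of these folds is therefore uncertain. Npr3, the natriuretic peptide clearance receptor, was 7.59-fold lower, Esm1 7.22-fold, Sncg, an adipocyte synuclein, 6.44-fold and Lbp, the lipopolysaccharide-binding protein, 5.70-fold lower. Cilp, Cyp2c67, Slc6a13, Nnat, Folh1 and Ccl8 were between 4.56 and 5.58-fold lower.

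Of 14905 genes measured in WAT, 326 were at least 2-fold higher and 316 at least 2-fold lower, with a median log2 ratio of 0.02 for all genes. With normexp the counts were 207 and 161. Without the skeletal muscle list they were 306 and 316, and without genes at least 8-fold higher in wild-type liver than in wild-type WAT they were 267 and 225. The muscle setting left out only the 23 measured members of that list, so Actc1 and any muscle gene outside the list stayed in. The last 2 settings were chosen after seeing the data.

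Thermogenic adipocyte genes were higher as a group in labelled-knockout WAT, with 14 of 29 measured genes at least 2-fold higher, 0 lower and a median of 0.96, above all random lists. Elovl3 (5.05), Ucp1 (3.04), the uncoupling protein of brown and beige fat, Dio2 (2.98), which activates thyroid hormone, and Cyp2b10 (2.37) led the list. Ucp1 was at 2.76 on the log2 scale in wild type and at 5.80 in the labelled knockout, relative to each array's 75th percentile. Skeletal muscle markers were higher in the same array, with 20 of 23 genes at least 2-fold higher and a median of 2.89, above all random lists. Pvalb was at 4.79, Ttn at 4.76, Myh4 at 4.73 and Ckm at 4.66. Some thermogenic genes are also used by muscle, and the 2 groups differed in the same pool.

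Oxidative phosphorylation genes, PPAR alpha targets and fatty acid synthesis genes were higher in labelled-knockout WAT too, in the array where skeletal muscle markers, from a tissue rich in oxidation genes, had a median of 2.89. PPAR alpha targets had a median of 0.45 with 7 of 38 genes at least 2-fold higher and 1 lower, led by the acyl-CoA thioesterases Acot1 (3.91), Acot3 (2.52) and Acot4 (1.90) and the peroxisomal enzyme Ehhadh (1.66). Oxidative phosphorylation genes had a median of 0.47 (0.30 with quantile normalization) with 38 of 38 genes within 2-fold, the largest being Ndufs8 (0.74) and Ndufa9 (0.71). Fatty acid synthesis genes had a median of 0.48 with Acacb (1.45) higher and Pnpla3 (-1.16) lower. These 3 lists lay above all random lists. The circadian list had a median of 0.34 (percentile 99.99) with 3 of 18 genes at least 2-fold higher, among them Cry1 (1.43) and Hlf (1.08). Cry1 was at 0.85 with normexp.

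General adipocyte genes did not stand apart. Their median was 0.10 (percentile 28.8), with 32 of 36 genes within 2-fold, while the mean was -0.14 because the 4 differing genes were all lower. These were Npr3 (-2.92), Sncg (-2.69), Lep (-1.99), which encodes leptin, and Mest (-1.38), a gene tied to fat expansion. With the mean in place of the median the list lay at percentile 0.020. The median turned to -0.04 with quantile normalization and to -0.07 with loess. Lipolysis and insulin action genes had a median of 0.23 (percentile 99.2), with Cish (1.93) higher and Npr3 (-2.92) lower, and lay at percentile 88.5 with the mean.

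Extracellular matrix, myeloid and endothelial genes were lower in labelled-knockout WAT, while the T and B cell list (percentile 33.9) and the blood vessel and nerve list (percentile 64.0) did not stand apart. Extracellular matrix genes had a median of -0.63 with 5 of 28 genes at least 2-fold lower, among them Timp1 (-2.02), Thbs1 (-1.67) and Col6a2 (-1.27), a chain of collagen VI. Macrophage and myeloid markers had a median of -0.77 with 5 of 29 genes at least 2-fold lower, among them S100a8 (-2.17), Lyz2 (-1.18) and Ccl2 (-1.15), and 2 higher, among them Cd14 (1.46). Endothelial and stellate markers had a median of -0.46, with Lyve1 at -1.32 and Vwf at -1.26. The brightest probe of Vwf read -0.73. All 3 lists lay below all random lists. Whether the WAT pools differed in depot or tissue makeup was not tested. Adipocyte progenitor markers had a median of -0.21 (percentile 0.69) with 18 of 19 genes within 2-fold and Ccn5 at 2.25, and were at percentile 31.0 with the mean.

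Liver-type transcripts were also lower in labelled-knockout WAT. Of 25 hepatocyte markers measured there, 13 were at least 2-fold lower and 0 higher, with a median of -1.002, below all random lists. Examples were Cyp3a11 (-1.81), Apoh (-1.65), Fgg (-1.63) and Ttr (-1.62), which encodes the thyroid hormone carrier transthyretin. Acute phase proteins had a median of -0.43, also below all random lists, with 9 of 23 genes at least 2-fold lower, led by Lbp (-2.51) and Saa3 (-2.15). Bile acid genes had a median of -0.34 (percentile 0.16, and 4.68 with the stricter filter on dim probes), led by Abcb11 (-1.87). In wild-type WAT the hepatocyte markers were at a small share of their wild-type liver signal, such as 3.15% for Alb and 0.326% for Apoa1, apart from Cyp2e1 at 34.0% and Trf at 33.6%.

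Of the lists of the study's own topic, choline metabolism did not stand apart in WAT and the methionine list was lower. Choline and phosphatidylcholine genes had a median of 0.05 (percentile 64.9), with 32 of 32 genes within 2-fold. Methionine cycle genes had a median of -0.15 (percentile 1.05), with Ftcd (-1.37), Bhmt2 (-1.21) and Gamt (-1.06) at least 2-fold lower. Ftcd was at -0.91 and Bhmt2 at -0.48 with normexp. The methionine list no longer stood apart with normexp (percentile 2.77), the stricter filter on dim probes (2.57) or the mean of the list (2.71), and was at percentile 8.55 without the genes much higher in liver, a setting chosen after seeing the data.

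Genes seen on 1 WAT array alone with a bound of at least 2-fold numbered 115 on the labelled-knockout array and 71 on the wild-type array. Fxyd4, a regulator of the sodium pump in kidney and gut epithelium, was at least 175-fold above wild type. The muscle genes Ckmt2, Myot and Casq1 were at least 41.3-fold, at least 19.2-fold and at least 17.6-fold above wild type. Sult2a1 was at least 7.90-fold and Cyp2c54 at least 6.28-fold above the labelled knockout. With normexp the counts were 30 and 8.

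**Figure D3:**
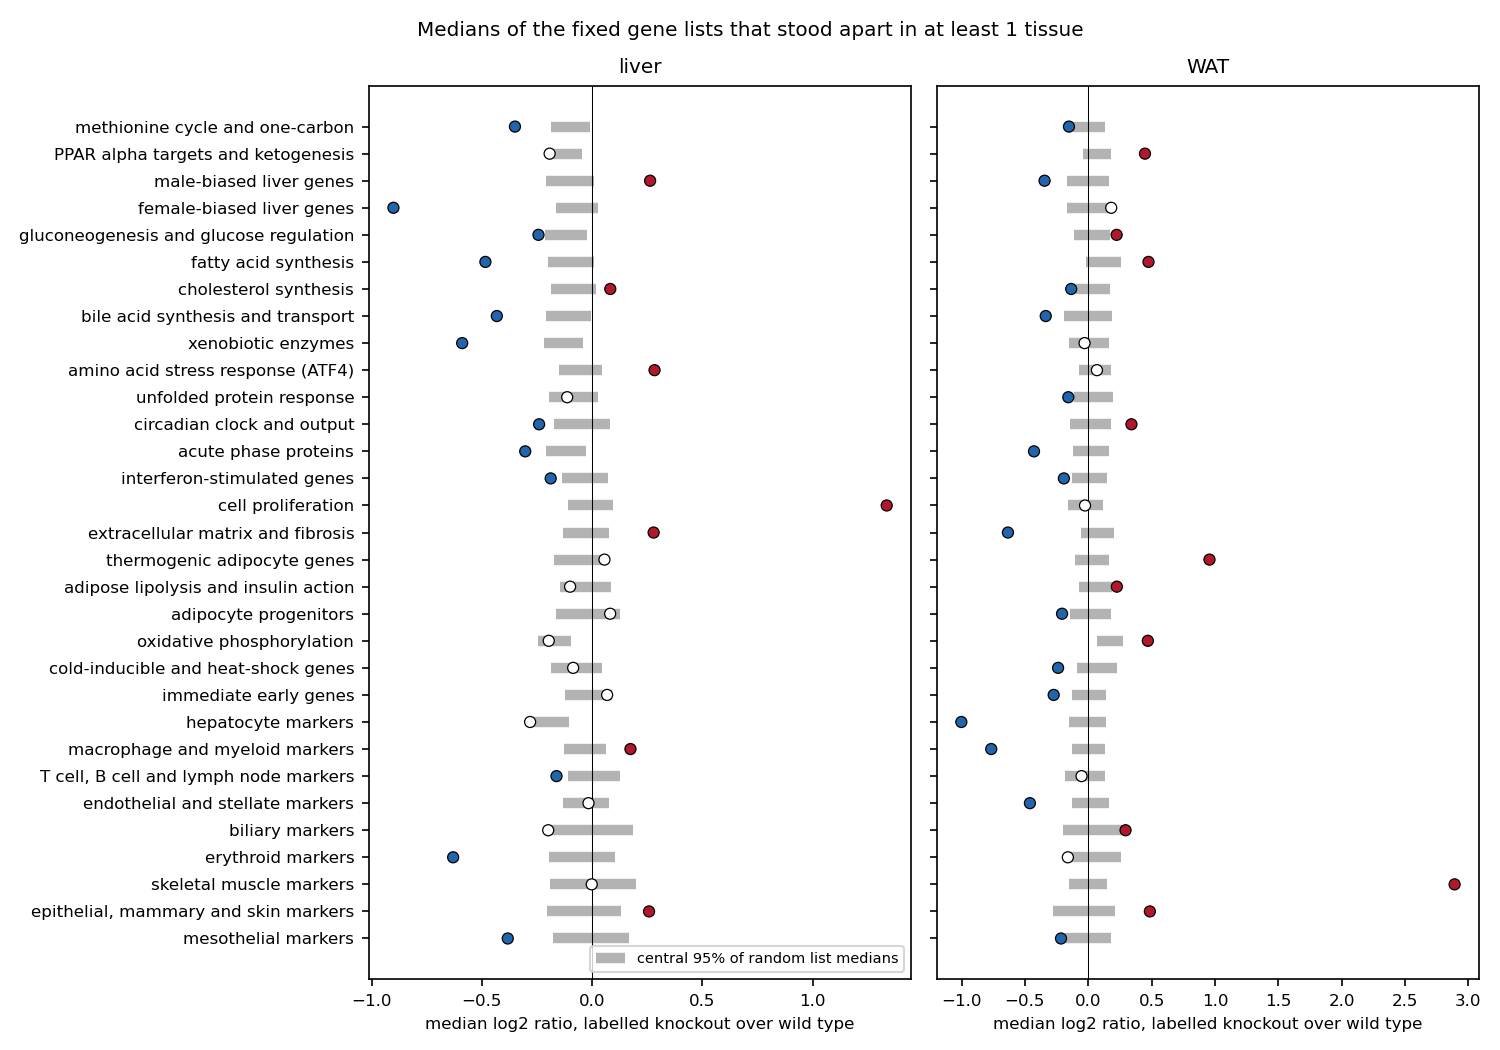
Median log2 ratio of labelled knockout to wild type (x axis) for each fixed gene list that stood apart in liver or WAT, with liver on the left and WAT on the right, on different scales. Grey bars span 10000 random list medians without the lowest and highest 2.5%, and filled points lie outside it (red higher, blue lower). Of 38 lists, 19 stood apart in liver and 25 in WAT, 7 and 10 of them on the higher side.

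The tissues shared little of the difference. Over 13825 genes measured on all 4 arrays, the log2 ratios of liver and WAT had a Pearson correlation across genes of -0.09 and a Spearman rho of -0.16, where genes are not independent replicates. Both ratios compare different arrays, so no control array is shared. The labels do not say whether liver and WAT came from the same animals, so the ratios may not be independent. At 2-fold, 9 genes were higher in both tissues where independent lists would share 4.28, and 7 were lower in both against 1.38. Another 9 were higher in liver and lower in WAT against 4.198, and 8 lower in liver and higher in WAT against 1.41. Sprr1a (3.88 in liver and 2.18 in WAT), S100g (1.87 and 3.44), Tuba8 (1.71 and 2.49), Cidea (2.44 and 1.63) and Bex1 (2.85 and 1.45) were higher in both. Hamp2 (-1.89 and -1.49), Wfdc21 (-1.49 and -1.60), Cyp3a16 (-1.30 and -2.38), Cyp2c68 (-1.19 and -2.65) and Cyp2c50 (-1.05 and -2.19) were lower in both. Some of these are liver-type transcripts that were dim in WAT, such as Cyp3a16 and Cyp2c50, at -2.99 and -2.61 in wild type. Hepatocyte markers were lower in labelled-knockout WAT as well, where some liver RNA in the wild-type pool stays open. The overlap was not recounted without genes high in liver, so it does not show a shared response to genotype. With normexp, Cidea was at 0.83 in liver and Bex1 at 0.81 in WAT, and Cyp2c50 was at -0.89 in liver with quantile normalization. The differences between the tissues were not tested.

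**Figure D4:**
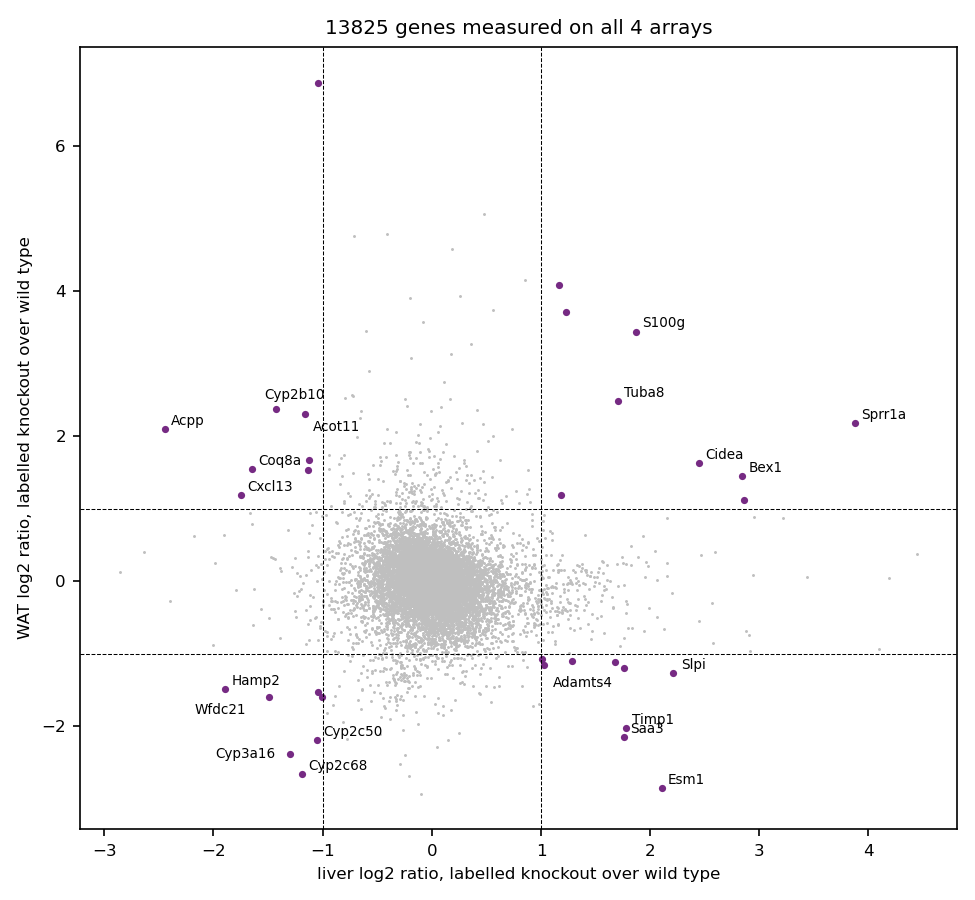
Each point is 1 of 13825 genes measured on all 4 arrays, with the log2 ratio of labelled knockout to wild type in liver on the x axis and in WAT on the y axis. Purple points are at least 2-fold different in both tissues, outside the dashed lines at -1 and 1. They fall in all 4 corners, with 9, 7, 9 and 8 genes.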

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

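The tests of explanations were chosen after the patterns were seen. For genes that fall after birth, the limits were set before the values of the listed genes were seen, and Afp and H19 were left out because theirs had been seen. The differences between the tissues were not tested, since each tissue had 1 array per genotype.

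Of the 38 gene lists, 7 stood apart in both tissues with opposite directions, and 6 in the same direction. The WAT minus liver difference of the medians was 0.96 for fatty acid synthesis, 0.58 for the circadian list and 0.47 for gluconeogenesis and glucose regulation, all higher in WAT. It was -0.94 for macrophage and myeloid markers, -0.91 for extracellular matrix, -0.61 for male-biased liver genes and -0.22 for cholesterol synthesis, all lower in WAT. The circadian list in liver, the male-biased list and the gluconeogenesis and glucose regulation list in WAT, and cholesterol synthesis in both tissues no longer stood apart on the same side under at least 1 other setting. Among single genes, 17 were at least 2-fold different in both tissues with opposite signs. The difference of the log2 ratios was 7.91 for Wfdc2 (its probes in WAT read 5.73 and 8.01), 4.54 for Acpp, 3.79 for Cyp2b10, 3.47 for Acot11, 3.19 for Coq8a, 2.94 for Cxcl13, 2.80 for Rgs16 and 2.66 for Zmynd12, all higher in WAT. It was -4.96 for Esm1, -3.91 for Saa3, -3.80 for Timp1, -3.47 for Slpi, -2.96 for Adamts4, -2.78 for Akr1c18, -2.38 for Cd209a, -2.18 for Ccl2 and -2.08 for Slamf9, all lower in WAT. With normexp Cd209a turned to -0.19 in liver, and 2-fold was no longer reached by Timp1 (0.85), Ccl2 (0.48), Adamts4 (0.71), Slamf9 (0.53) or Wfdc2 (-0.96) in liver, nor by Zmynd12 (0.79), Cxcl13 (0.97), Akr1c18 (-0.84), Adamts4 (-0.89), Cd209a (-0.82) or Slamf9 (-0.90) in WAT. Acpp in WAT was at 0.61 without a filter on background, and Rgs16 in liver at -0.96 with quantile normalization.

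The higher thermogenic genes in labelled-knockout WAT went with higher skeletal muscle markers. Muscle in that pool as the whole source is argued against by 9 measured thermogenic genes taken as not used by muscle, whose median log2 ratio was 1.996. Of these, 7 were at least 2-fold higher, among them Ucp1 (3.04) and Elovl3 (5.05), while Letmd1 was at 0.77 and Adrb3 at -0.20. The 9 genes were chosen after the pattern was seen, and Elovl3, Ucp1 and Cyp2b10 already led the thermogenic list. Their place above all random lists therefore adds no support. Muscle tissue in the pool as the source of the muscle genes themselves was not tested. Brown fat taken with the white fat stays open and cannot be told apart from a difference within white fat. The reason is that the brighter probe of Zic1, a brown fat gene, had a log2 ratio of 0.26 at a level near the dimmest genes. The fat depot is not given, so it is unknown whether both WAT pools came from the same depot. The epithelial list (median 0.49) and the mesothelial list (-0.22) also stood apart in WAT. A differing makeup of the 2 pools therefore cannot be told apart from genotype. A difference by genotype stays among the open explanations, as untested.

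The lower hepatocyte transcripts in labelled-knockout WAT would arise if the wild-type WAT pool held some liver RNA. Alb, chosen after its values were seen, needed the largest share of liver among the markers. That share would bring more signal than wild-type WAT showed for 83.3% of the other hepatocyte markers (20 of 24). With the largest share as the measure, most other markers were likely to fall below it. The count therefore speaks only against a single share as large as that for Alb. A small share stays open. The shares needed by the 21 markers lower in the labelled knockout ran from 0.0455% for Tat to 2.10% for Alb, with an SD of 1.56 on the log2 scale. All 25 markers were also measured in labelled-knockout WAT, where Cyp2e1 was at 66.6% of its wild-type liver signal, so expression by fat itself keeps a single share of liver RNA from being excluded. A difference by genotype stays open, as untested.

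The lower female-biased and higher cell cycle genes in labelled-knockout liver might come from the makeup of the pools. Male animals in the labelled-knockout liver pool, as the whole source, are argued against by 0 of 4 Y-linked genes (Ddx3y, Eif2s3y, Uty and Kdm5d) well above background. The data hold no male sample that shows these probes at work, however. Sry was well above background at a dim level on all 4 arrays, wild-type ones included (log2 ratio -0.37 in liver). It therefore does not set the labelled-knockout pool apart. Males as the whole source are also argued against by Xist, which was 18.8% lower where the female-biased median would need 46.5% fewer female transcripts. A smaller share of males is not excluded by Xist, which was lower in labelled-knockout WAT too. Erythroid precursors as the dividing cells are argued against by the erythroid list's median of -0.63, with 11 of 12 genes lower and Tfrc, which dividing cells of other types also use, at 0.90. A less mature liver stays open, because 13 genes known to fall after birth had a median of 0.04 at percentile 76.5, while Afp and H19, left out of that list, were at 2.19 and 2.15. The 2 probes of H19 differed, at 0.34 and 3.97. A difference by genotype stays among the open explanations, as untested.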

How the results depend on the processing

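The settings without genes high in liver and without the muscle list were chosen after seeing the data. No paired analysis was possible because the labels pair no animals or replicates across groups. A fit of genotype with tissue as a block was not run. With 1 array per group no array could be left out in turn. The slide as a block was not run, since all arrays lay on 1 slide. Of 19 lists that stood apart in liver, 12 did so under every setting, and 15 of 25 in WAT. These included proliferation, ATF4 targets, female-biased genes and fatty acid synthesis in liver, and thermogenic, muscle, hepatocyte, extracellular matrix and macrophage lists in WAT. Over 946 list percentiles, 884 kept their call, which includes lists that did not stand apart in either setting. Another 30 no longer stood apart and 25 newly did so, without crossing the middle of the random lists. The other 7 crossed the middle and stood apart before or after. Of these, only male-biased genes in WAT stood apart both times, at percentile 0.080 and then at 98.5 without genes high in liver. Of 190 named ratios of at least 2-fold, 142 stayed so under every setting. Of 3475 named ratios recomputed, 168 moved by more than the spread between probes, 138 of them with normexp, where 123 came closer to 0, and 2 more turned, Ccl4 and Cd209a in liver. Pnpla7 ran from -0.21 to -0.08 in liver and from -1.01 to -0.88 in WAT. The correlation across genes was -0.09, ran down to -0.132 with the stricter dim filter and was -0.0261 without a filter on background. Over quantile and loess normalization, the median of each array, the 75th percentile over measured probes, the brightest probe, all spots kept and the authors' table, the higher genes in liver numbered between 232 and 289 and the lower between 105 and 137. Signal over background limits the dim genes. Normexp moved the median of all liver genes from -0.03 to -0.18. List medians moved too, also where the list still stood apart, as for proliferation in liver (1.34 to 0.85 with normexp), bile acid genes in WAT (-0.34 to -0.12 with normexp), heat-shock genes in WAT (-0.24 to -0.13 with normexp), the epithelial list in WAT (0.49 to 0.30 with normexp) and erythroid markers in liver (-0.63 to -0.28 without a filter on background).

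Except where fewer or more genes entered by construction, the cause was not tested. With normexp, 98 genes were higher and 210 lower in liver, and 207 and 161 in WAT. Genes seen on 1 array with a 2-fold bound numbered 1 (labelled knockout) and 145 (wild type) in liver, and 30 and 8 in WAT. Genes differing in both tissues numbered 3 (both higher), 4 (both lower) and 4 (liver higher, WAT lower). In liver Ccl4 turned from 1.03 to -0.25 and Cd209a from 1.28 to -0.19. The epithelial list in liver went from percentile 99.9 to 31.9. The hepatocyte median between tissues on the labelled-knockout arrays was -8.36. Without a filter on background, which adds dim probes, liver counts were 620 and 381 and WAT counts 624 and 622. Shared genes numbered 52 (both higher), 53 (both lower), 30 (liver higher, WAT lower) and 38 (the opposite). Female-biased genes in WAT went from percentile 97.3 to 1.17, and the adipocyte medians between tissues were 5.03 on wild-type and 4.35 on labelled-knockout arrays. A fold limit of 1.5 gave 648 higher and 529 lower genes in liver, 892 and 1156 in WAT, and 42, 66, 95 and 74 shared genes in the same order of patterns. A limit of 3 gave 76 and 38, 131 and 68, and 4, 0, 3 and 1. The stricter dim filter left 5 genes higher and 3 lower in both tissues. Quantile normalization, and likewise the 75th percentile over measured probes, left 4 lower in both. With the median of each array the medians between tissues on wild-type arrays were 3.87 for adipocyte and -7.96 for hepatocyte genes. With the mean of a list, PPAR alpha targets in liver went from percentile 6.17 to 99.9, the growth hormone list from 4.67 to 98.8 and apolipoproteins from 9.87 to 97.8. Without genes high in liver, male-biased genes in WAT went from percentile 0.080 to 98.5 and xenobiotic enzymes from 29.2 to 100, while without a filter on background xenobiotic enzymes lay below all random lists.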

Other observations

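Further fixed lists stood apart in WAT on the lower side. Heat-shock and cold-inducible genes had a median log2 ratio of -0.24 (percentile 0.050), with the chaperones Cryab at -1.21 and Hsph1 at -1.08. Immediate early genes had a median of -0.27 (percentile 0.020), with Egr2 at -1.60. Interferon-stimulated genes were lower in both tissues, with medians of -0.19 in liver (percentile 0.21) and -0.19 in WAT (percentile 0.40) and 24 of 24 genes within 2-fold in each. The unfolded protein response list in WAT had a median of -0.16 (percentile 0.76) and cholesterol synthesis one of -0.13 (percentile 0.79), with 0 genes at 2-fold in either. Cholesterol synthesis in WAT no longer stood apart among unmatched random lists (percentile 2.60) or with the mean of the list (4.14). Male-biased liver genes in WAT had a median of -0.35 (percentile 0.080), with Mup3 at -1.09 and Elovl3 at 5.05, and lay at percentile 98.5 without genes high in liver, a setting chosen after seeing the data. The mesothelial list had a median of -0.38 in liver (percentile 0.020), with Slpi at 2.21, and -0.22 in WAT (percentile 1.30), with Slpi at -1.26. It lay at percentile 10.2 in liver with the mean of the list and at 2.73 in WAT with quantile normalization. Jchain, the joining chain of secreted antibodies, was at -1.96 in WAT, while the T and B cell list there lay at percentile 33.9.

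Epithelial genes were higher in labelled-knockout WAT, where a difference in the makeup of the pools was not tested. The epithelial list had a median of 0.26 in liver (percentile 99.9, but 31.9 with normexp) and 0.49 in WAT, above all random lists, where Cldn3 was at 4.58 and Krt18 at 2.17, the 2 of 11 genes at 2-fold. In WAT it lay at percentile 96.8 without genes high in liver, a setting chosen after seeing the data. The biliary list in WAT, which shares Epcam and Cldn4 with it, had a median of 0.29 (percentile 98.5), with Cldn7 at 1.03, and lay at percentile 92.3 with normexp, where Cldn7 was at 0.82. In WAT the gluconeogenesis and glucose regulation list had a median of 0.22 (percentile 99.6), with Ppargc1a at 1.35 and Fbp1 at -1.29. It lay at percentile 91.3 with quantile normalization. The circadian list in liver had a median of -0.24 (percentile 0.19) with 17 of 17 genes within 2-fold, and no longer stood apart with normexp (percentile 2.73), the mean of the list (7.19) or no filter on background (8.64).

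The remaining lists did not stand apart with the settings of the report, though some did with others. In liver, the percentiles were 4.67 for the growth hormone list, 97.0 for thermogenic genes, 3.48 for adipocyte genes, 10.9 for lipolysis, 91.2 for adipocyte progenitors, 27.8 for oxidative phosphorylation, 37.2 for heat-shock genes, 93.7 for immediate early genes, 9.87 for apolipoproteins, 52.1 for skeletal muscle, 7.55 for exocrine pancreas, 41.3 for gonadal genes and 25.9 for vessel and nerve markers. Adipocyte genes in liver stood apart on the lower side with normexp (percentile 0.080), quantile normalization (0.66), loess (0.41), no filter on background (1.02) and unmatched random lists (0.78), and lipolysis genes with normexp (0.11) and quantile normalization (1.53). Among unmatched random lists, oxidative phosphorylation (0.010), apolipoproteins (0.11) and the growth hormone list (2.45) stood apart on the lower side. Exocrine pancreas markers did so with the mean of the list (1.03). Thermogenic genes stood apart on the higher side with the mean (99.97) and with quantile normalization (97.8), and immediate early genes without a filter on background (99.2). The growth hormone list and apolipoproteins moved to the higher side with the mean (98.8 and 97.8). Fst in liver was at 1.33, Apoa4 at 2.07, Atf3 at 2.13 and Bmp8b at 2.38. In WAT they were 72.4 for the growth hormone list, 97.3 for female-biased genes, 29.2 for xenobiotic enzymes, 55.1 for ATF4 targets, 43.1 for proliferation, 54.0 for apolipoproteins, 2.84 for erythroid markers, 77.8 for exocrine pancreas, 74.1 for gonadal genes and 64.0 for vessel and nerve markers. Erythroid markers in WAT stood apart on the lower side under 5 other settings, with percentiles between 0.42 and 1.13. Xenobiotic enzymes in WAT lay below all random lists without a filter on background. With genes seen on 1 array set at their bounds, the female-biased median in WAT went from 0.18 to -0.22, and the erythroid median from -0.16 to -0.26. Among probes without a gene symbol, 48 of 5244 in liver were at least 2-fold higher and 49 lower, and 86 and 50 of 5542 in WAT.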
